A study of Mus musculus with 18 samples.

How the data were processed

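Gene expression was measured in whole mouse testis at 6 stages, E12.5, E15.5, P7, P14, P21 and adult, with 3 arrays per stage and 18 arrays in all. Per the labels' protocols, testes were dissected fresh and frozen, RNA was extracted with Trizol and treated with DNase, and ribosomal RNA was removed. The RNA was then copied by random priming into cRNA carrying the dye Cy3, so that signal was not restricted to the 3′ ends of transcripts. Each sample was hybridised alone to a 1-colour Agilent array, and the images were read with Agilent Feature Extraction 11.0.1.1, per the submitters' processing notes. The labels describe the arrays as measuring lncRNAs and mRNAs together. The titles number the replicates 1 to 3, and no label says that they came from separate animals or litters. P-values therefore measure only the spread between these samples, which may be technical.

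The deposited table held 1 value for each of 37820 probes in each of the 18 arrays, with no missing value. The authors deposited these values on what was taken to be a log2 scale. The log base, the normalization and the filter on probes are not given in the sources used here. Base 2 was inferred from the range of the values, from 2.38 to 18.34. Array medians ran from 7.79 to 8.00. Between 79.4% and 90.4% of the values of an array recurred exactly in another array, a pattern that quantile normalization over a larger set of probes followed by removal of some probes would leave. The values were used as deposited. Scanner files and detection flags were not used here, so no probe could be called present or absent, and a probe with a low value has no stated limit of detection. The number of arrays limits the precision, and a depth in reads does not apply.

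None of the 37820 probe identifiers matched the gene tables used here (0 matched), and probes were therefore named by their identifiers. Identifiers were sorted into 4 families by their text. ASMM9PARTA and a number made up 34232 probes, 2480 probes had lincRNA in the identifier, 581 were sequence accessions and 527 were CUST and a number. The 24 gene lists and cell type markers fixed before the data were examined were not tested. The shift of X-linked genes, the comparison of noncoding with coding probes, and the pairs of genes on opposite strands also needed gene names and were not run. In their place, probes with lincRNA in the identifier were compared with all other probes, a comparison chosen after the identifiers were seen. The ASMM9PARTA family was not divided, and it can hold lncRNA and mRNA probes alike. The rule for named genes was fixed on gene symbols. In its absence, 4 probes were named, the 2 with the largest rise and the 2 with the largest fall from E12.5 to adult among called probes whose values did not overlap between these stages.

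A linear model with 1 mean per stage was fitted to all 18 arrays with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with the default prior). It left 12 residual degrees of freedom per probe, to which the prior added 3.20. The 5 adjacent pairs of stages and adult against E12.5 were tested as 6 contrasts. A probe was called at a Benjamini-Hochberg adjusted p below 0.05 within the comparison and a change of at least 1 on the log2 scale, which is 2-fold. The F test over the 5 adjacent contrasts asked whether a probe differed between the 6 stages, and a called probe also had a range of at least 1 between its stage means. Each probe that differed was assigned to the stage of its highest mean, and each probe called between adult and E12.5 to the interval with its largest change. Probes with lincRNA in the identifier were compared with other probes by Fisher's exact test, two-sided, and by a Mantel-Haenszel odds ratio stratified by 5 equal groups of probes ranked on mean signal, with 95% confidence intervals. Probes are not independent of each other, so these intervals are too narrow. Principal components were computed from all probes without scaling. Plots were drawn with matplotlib 3.10.9.

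The fit was tested on simulated data before use, with 100 of 37820 probes changed by 1.5 and another 100 by 2.5 on the log2 scale. With equal spread in all arrays, adult against P21 recovered 51% of the smaller and 81% of the larger changes, and 7.69% of the calls were false. With the spread of each real array, 42 unchanged probes were called in adult against P21, 24.0% of its simulated calls, and 40 in adult against E12.5, 21.7% of its simulated calls. The false share with as many changed probes as the real comparisons called was not simulated.

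Alternatives fixed before the data were examined were the replicate number as a block, a fit of only the 6 arrays compared, a trended and robust prior, quantile normalization of the deposited values again, centring of each array on its median, removal of the 25% of probes with the lowest mean (mean signal up to 6.53), no minimum change, an adjusted p below 0.01, limma's treat test against a 2-fold change, adjustment over all 6 comparisons together, and each array left out in turn for the counts of called probes and the named probes. Added after the data were seen were a fit without E12.5 replicate 2 and P21 replicate 1, limma's array weights, a fit with E12.5 replicates 1 and 3 averaged to 1 array, the alternatives for the lincRNA probes and for the interval of the largest change, and each array left out in turn for the stage of the highest mean and the changes of at least 8-fold. Arrays had no scan date, slide or other batch label in the sources used here, so no batch was tested.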

Results

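Transcript levels were measured on 18 arrays of whole mouse testis, 3 at each of 6 stages. The series asks which long noncoding RNAs and mRNAs change as the male germline develops. The stages run from E12.5, when testis cords have recently formed, and E15.5, when fetal germ cells enter mitotic arrest, to the first wave of spermatogenesis at P7, P14 and P21 and the complete process in the adult. As background, spermatogonia are the most advanced germ cells at about P7, spermatocytes in meiotic prophase at about P14 and round spermatids at about P21. Whole testis also holds Sertoli, Leydig and other somatic cells, whose share differs between ages. Values are the authors' log2 signals of 37820 probes, and changes are differences of stage means on the log2 scale.

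The arrays grouped mainly by stage, and the adult testis was the most distant. The first principal component held 59.0% of the variance and placed the fetal arrays at one end, followed by P7, P14, P21 and adult in order of age. The second held 14.3% and the third 9.88%. The mean correlation across probes with the adult arrays was 0.644 for E12.5, 0.673 for E15.5, 0.704 for P7, 0.737 for P14 and 0.877 for P21. The order of age did not hold for every pair of stages, since E12.5 correlated better with P7 (mean r = 0.924) than with E15.5 (0.907). Probes are not independent replicates in these correlations. Replicates were closest at P14, with r from 0.993 to 0.995, and most variable at E12.5 (0.931 to 0.997) and P21 (0.924 to 0.982). E12.5 replicate 2 stood apart from its stage. It correlated best with E15.5 replicate 2 (r = 0.956) and less with the other E12.5 arrays (mean r = 0.931). Its correlations with the P7 arrays, from 0.942 to 0.948, were also above those with its own stage. E12.5 replicates 1 and 3 differed by an SD of 0.23, less than any other pair of arrays of one stage. P21 replicate 1 also stood apart, with a mean r of 0.936 to the other P21 arrays, which correlated with each other at 0.982. Adult replicate 1 showed a similar pattern, with a mean r of 0.952 to the other adult arrays. Those correlated with each other at 0.988. Adult replicate 1 was kept in the fit without E12.5 replicate 2 and P21 replicate 1. At E12.5 that fit rests on replicates 1 and 3 alone.

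**Figure D1:**
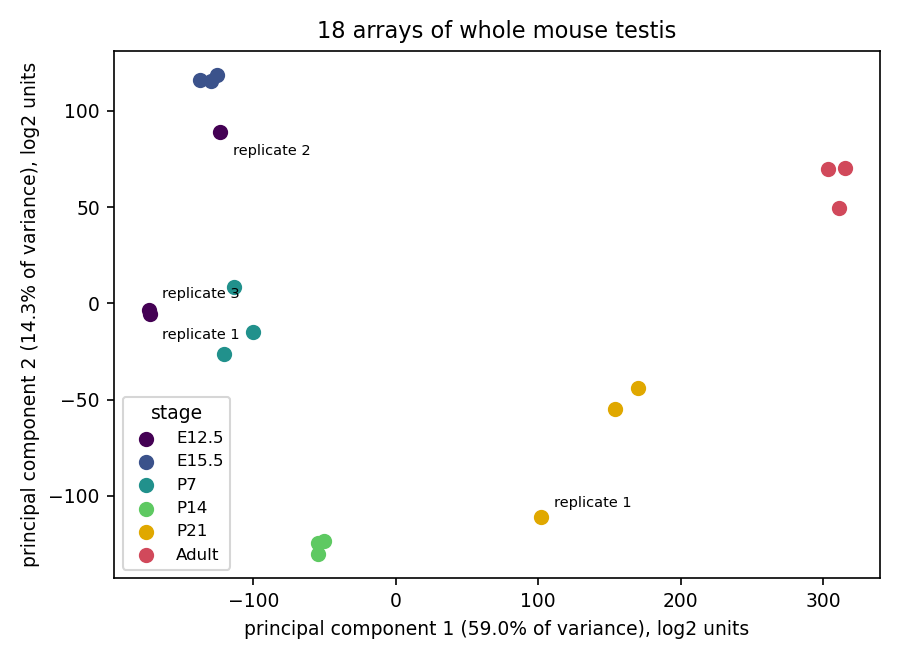
The 18 arrays on the first and second principal components of all 37820 probes, in log2 units, with one point per array coloured by stage. Adult arrays lie farthest along the first component, from 303.84 to 315.43, E12.5 replicate 2 lies near the E15.5 arrays, and P21 replicate 1 lies at 102.02 against 153.79 and 170.42 for the other P21 arrays.

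Most probes changed over testis development. Of 37820 probes, 27890 (73.7%) differed between the 6 stages in limma's F test at an adjusted p below 0.05 with a range of at least 2-fold between stage means. The range reached 8-fold in 11408 probes and 32-fold in 3169. Of the probes that differed, 6841 were called in no adjacent interval, so that their change was spread over several intervals or passed the test only over all stages.

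Signal was highest in the fetal testis or in the adult for most of these probes. The adult mean was the highest for 7050 probes (25.3%), the E15.5 mean for 6617 (23.7%) and the E12.5 mean for 5590. P7, P14 and P21 held the highest mean of 2706, 2949 and 2978 probes. The adult stood out more among 5168 probes whose highest stage exceeded every other by at least 2-fold, of which 2718 (52.6%) were highest in the adult, 924 at E12.5, 925 at E15.5, 148 at P7, 217 at P14 and 236 at P21. These counts carry no test. Without E12.5 replicate 2 and P21 replicate 1, 6973 probes were highest at E12.5 and 6792 in the adult, so the order of these stages depended on those arrays. P21 then held the highest mean of 4406 probes and P14 of 2197, so the counts at P14 and P21 depended on those arrays too.

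From E12.5 to E15.5, as fetal germ cells stop dividing, 7602 probes (20.1%) changed at least 2-fold. Signal rose for 4025 and fell for 3577. The median change was 1.59 among rises and −1.89 among falls, and 640 falls and 428 rises reached 8-fold. These numbers depended on single arrays, with 1286 falls and 599 rises of at least 8-fold without E12.5 replicate 2, and 362 falls and 367 rises without E12.5 replicate 1. The values of the stages did not overlap for 38.4% of all probes, against 10% by chance for 3 arrays against 3. The 4 named probes did not pass the test here (adjusted p from 0.806 to 0.880, limma). ASMM9PARTA010514 was at 14.20 ± 0.56 at E12.5 and 14.32 ± 0.12 at E15.5, and ASMM9PARTA033460 was at 14.67 ± 0.08 and 14.55 ± 0.03 (log2 signal, SD, n = 3). The number called depended on single arrays. It was 5068 without E12.5 replicate 1 and 10780 without E12.5 replicate 2, and 5095 with E12.5 replicates 1 and 3 averaged to 1 array. Without E12.5 replicate 2 the stage rests on replicates 1 and 3, which differed by an SD of 0.23, so the spread in that fit may be understated.

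From E15.5 to P7, across birth and the return of germ cells to division, 5951 probes (15.7%) changed. Signal rose for 2838 and fell for 3113, with a median of 1.66 among rises and −1.52 among falls. The balance turned without the dimmest 25% of probes (2668 higher and 2491 lower) and without E12.5 replicate 2 and P21 replicate 1 (3666 and 3477), so neither direction prevailed. Changes of at least 8-fold numbered 284 rises and 208 falls, and 209 of each without P7 replicate 1. The fetal signal of ASMM9PARTA010514 was lost mainly in this interval: its level fell by 6.39 (SE 0.26, adjusted p = 1.23e-09) to 7.93 ± 0.09 (SD, n = 3) at P7. ASMM9PARTA033460 fell by 2.52 (SE 0.25, adjusted p = 4.13e-06) to 12.03 ± 0.07. Values did not overlap between the stages for 49.4% of all probes, against 10% by chance.

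From P7 to P14, when germ cells enter meiosis, 4858 probes (12.8%) changed, the fewest of the 5 adjacent intervals in the fit over 18 arrays. Signal rose for 2348 and fell for 2510, with medians of 1.52 and −1.46. This balance also turned, with 450 higher and 348 lower at P14 in limma's treat test of changes beyond 2-fold, and 3132 and 2908 without E12.5 replicate 2 and P21 replicate 1. There were 212 rises and 108 falls of at least 8-fold. ASMM9PARTA033460 fell by 2.80 more (SE 0.25, adjusted p = 1.30e-06), while the probes that rose later were still low at P14, ASMM9PARTA025997 at 7.14 ± 0.07 and ASMM9PARTA036091 at 7.11 ± 0.24 (SD, n = 3). At an adjusted p below 0.01 the number called was 3195. With only the 6 arrays of each pair fitted, 6064 were called here and 5570 from E12.5 to E15.5, so the interval with the fewest changes depended on the fit.

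From P14 to P21, when round spermatids appear, 8894 probes (23.5%) changed, and the rises were large. Signal rose for 3481 probes with a median of 2.05 and fell for 5413 with a median of −1.59. Rises of at least 8-fold numbered 1059, and falls of that size 75. ASMM9PARTA036091 rose by 7.29 (SE 0.56, adjusted p = 6.45e-08) to 14.40 ± 0.65 and ASMM9PARTA025997 rose by 5.66 (SE 0.42, adjusted p = 4.33e-08) to 12.79 ± 0.04 (SD, n = 3). The number of steep falls depended on every P21 array. It was 662 without P21 replicate 1 (with 1144 rises of that size), 7 without P21 replicate 2 and 31 without P21 replicate 3. In limma's treat test of changes beyond 2-fold the balance turned, with 1777 higher and 607 lower at P21.

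From P21 to adult, as spermatids complete their differentiation and the testis reaches full size, 11705 probes (30.9%) changed, the most of the adjacent intervals in the fit over 18 arrays. Signal fell for 7916 probes with a median of −1.48 and rose for 3789 with a median of 2.06. The rises again included more steep changes, with 1041 rises and 110 falls of at least 8-fold. Without P21 replicate 2 there were 1111 and 197. ASMM9PARTA025997 rose by a further 1.90 (SE 0.42, adjusted p = 0.00208). The median change of all probes was −0.33 in the deposited values and −0.13 after quantile normalization again. The share of called probes that were higher in the adult was 32.4% in the deposited values, 40.3% with each array centred on its median and 42.9% after quantile normalization again, and in the treat test the balance turned, with 1745 higher and 1244 lower. With only the 6 arrays of each pair fitted, 7588 probes were called here and 8007 from P14 to P21, which turns their order. Without Adult replicate 1, 13832 probes were called from P21 to adult.

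**Figure D2:**
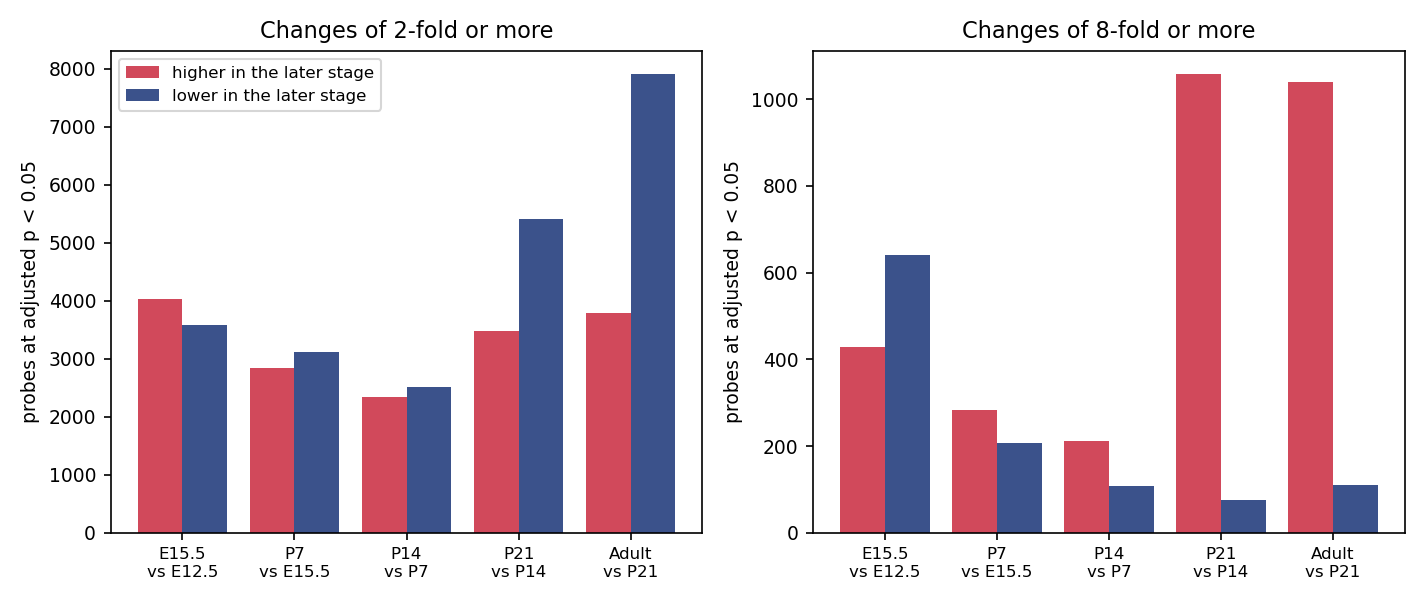
Probes called in each interval between adjacent stages, with limma's adjusted p below 0.05, drawn as bars for probes higher and lower in the later stage. At 2-fold or more falls outnumber rises from P14 to P21 (5413 against 3481) and from P21 to adult (7916 against 3789), while at 8-fold or more rises outnumber falls (1059 against 75 and 1041 against 110), and without P21 replicate 1 the 75 steep falls become 662.

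Adult and E12.5 testis differed at 21919 probes (58.0%). Signal was higher in the adult for 9033, with a median change of 2.42, and lower for 12886, with a median of −2.40. Changes of at least 8-fold numbered 3420 rises and 4404 falls. ASMM9PARTA025997 rose by 9.02 (SE 0.42, adjusted p = 3.70e-11), from 5.67 ± 1.24 to 14.69 ± 0.02, and ASMM9PARTA036091 rose by 8.96 (SE 0.56, adjusted p = 1.05e-09), from 5.67 ± 0.34 to 14.63 ± 0.16. ASMM9PARTA010514 fell by 10.42 (SE 0.26, adjusted p = 5.35e-14), from 14.20 ± 0.56 to 3.79 ± 0.33, and ASMM9PARTA033460 fell by 9.64 (SE 0.25, adjusted p = 6.14e-14), from 14.67 ± 0.08 to 5.03 ± 0.61 (log2 signal, SD, n = 3). Values did not overlap between the stages for 66.8% of all probes, against 10% by chance. Both rising probes started and both falling probes ended below 6.53, in the range of the dimmest 25% of probes. Their changes may be understated where that level is background, which was not measured. Without E12.5 replicate 2 the rise of ASMM9PARTA025997 was 8.31. The median change of all probes was −0.29 in the deposited values and −0.04 after quantile normalization again, which gave 9960 higher and 11376 lower.

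Most of the difference between adult and E12.5 arose after P14. Among the 9033 probes higher in the adult, the median of stage means was 7.29 at E12.5, 7.72 at E15.5, 7.75 at P7, 8.19 at P14, 9.22 at P21 and 10.26 in the adult. Among the 12886 lower in the adult it was 9.84 at E12.5, 9.55 at E15.5, 9.41 at P7, 9.12 at P14 and 6.91 in the adult. The largest single rise fell between P14 and P21 for 2466 (27.3%) of the first set and between P21 and adult for 2859 (31.7%). The largest fall lay between P21 and adult for 5280 (41.0%) of the second set, between P14 and P21 for 2953 (22.9%) and between E12.5 and E15.5 for 2208 (17.1%). These counts carry no test. Without P21 replicate 1 the largest rise came between P14 and P21 for 2998 probes and between P21 and adult for 2436, which turns their order. The lead of the last interval in falls also depended on P21 arrays: the largest fall came between P14 and P21 for 4384 probes and between P21 and adult for 4530 without P21 replicate 1, and for 1904 and 6311 without P21 replicate 2. Between E12.5 and E15.5 the largest rise was found for 2095 and the largest fall for 3396 without E12.5 replicate 2.

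**Figure D3:**
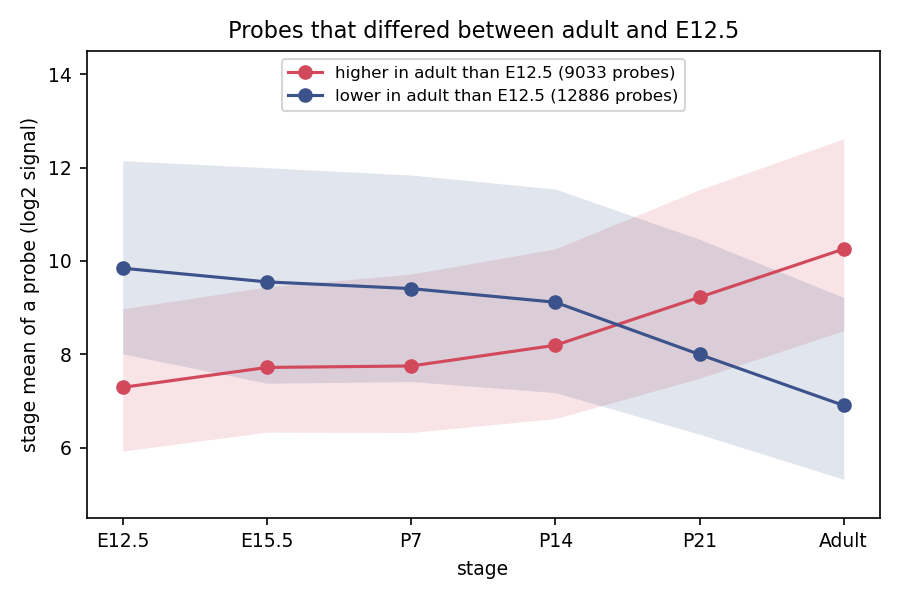
Stage means of the 9033 probes higher and the 12886 probes lower in adult than at E12.5, in log2 signal, with the line at the median and the band from the lower to the upper quartile across probes. The medians move from 8.19 to 10.26 and from 9.12 to 6.91 between P14 and adult, and by less before P14.

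Probes with lincRNA in the identifier, for long intergenic noncoding RNAs, changed less often than other probes. Of 2480 such probes 1314 (53.0%) differed between the 6 stages. From P14 to P21 6.21% of them were called against 24.7% of other probes (odds ratio 0.202, 95% interval 0.170 to 0.238, adjusted p = 2.76e-124, Fisher's exact test), and between E12.5 and adult 41.2% against 59.1% (0.484, 0.446 to 0.527, adjusted p = 8.73e-67). The odds ratio was 0.357 from E12.5 to E15.5, 0.519 from E15.5 to P7, 0.661 from P7 to P14 and 0.489 from P21 to adult, with an adjusted p of at most 1.59e-09 in these comparisons. The probes were dimmer, with a median mean signal of 6.96 and 39.6% of them among the 25% dimmest. Stratified by mean signal the odds ratio was 0.237 from P14 to P21 (95% interval 0.201 to 0.280) and 0.584 between E12.5 and adult (0.536 to 0.637). In the brightest of 5 strata of mean signal, 73.9% of 203 lincRNA probes and 70.3% of other probes were called between E12.5 and adult. Low shares were not particular to lincRNA probes. Among sequence accessions 9.64% were called from P14 to P21, 7.75% from P7 to P14 and 45.3% between E12.5 and adult. The shares of CUST probes were 22.4%, 16.3% and 55.4%. The lincRNA probes included 625 pairs on both strands of one number, and whether both strands are transcribed was not tested.

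The lincRNA probes that changed between E12.5 and adult more often rose. Of 1022 called, 581 (56.8%) were higher in the adult, against 40.4% of the other called probes (odds ratio 1.94, adjusted p = 4.33e-24, Fisher's exact test). Such a share was not particular to lincRNA probes, since 165 of 292 called CUST probes (56.5%) were also higher. Among called sequence accessions it was 46.4%, and among called ASMM9PARTA probes 40.1%. The shares of lincRNA and of all other probes were 67.7% and 45.7% after quantile normalization again. They were 62.5% and 43.7% with each array centred on its median, and 62.8% and 42.0% without E12.5 replicate 2 and P21 replicate 1. In the deposited values called lincRNA probes also rose more often than others from E12.5 to E15.5 (67.3% against 52.5%, adjusted p = 6.04e-05), from E15.5 to P7 (56.6% against 47.3%, adjusted p = 0.00981) and from P7 to P14 (58.2% against 47.9%, adjusted p = 0.00520), and the shares kept this order under both rescalings and without the pair of arrays. Among probes that differed between stages, the adult mean was the highest for 36.8% of lincRNA probes and 24.7% of others, and the E12.5 mean for 9.97% and 20.5%. Stratified by mean signal the odds ratio was 1.76 for a highest mean in the adult (95% interval 1.57 to 1.98, adjusted p = 1.09e-21, Mantel-Haenszel test) and 0.417 for a highest mean at E12.5 (0.347 to 0.502). For a highest mean at P7, P14 or P21 the adjusted p was 0.157, 0.263 and 0.168, and at E15.5 the odds ratio was 0.999 (0.877 to 1.14). From P14 to P21 and from P21 to adult, the share of called lincRNA probes that rose (38.3% and 32.8%) did not pass the test against other probes (39.2% and 32.4%). After quantile normalization again they were 49.4% against 42.6% and 51.1% against 42.6%, and with each array centred on its median the share of lincRNA probes was also the higher in both, at 45.8% and 45.9%. Without P21 replicate 1 they were 55.3% against 36.9% and 17.4% against 31.5%, and 20.2% of lincRNA probes against 14.1% of others had their highest mean at P21. The direction of lincRNA probes around P21 therefore depended on the scaling and on this array.

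**Figure D4:**
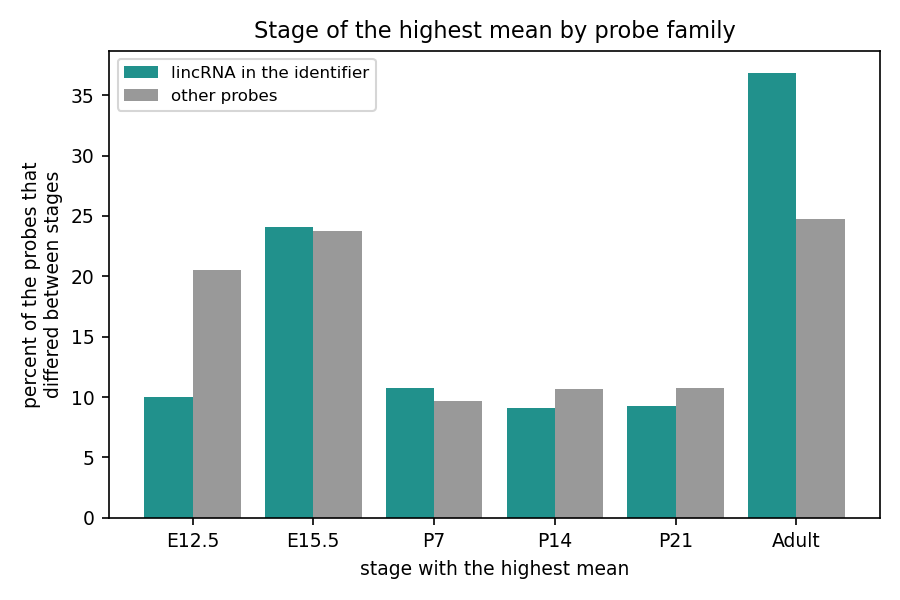
Stage of the highest mean among probes that differed between the 6 stages, as a percent of 1314 probes with lincRNA in the identifier and of 26576 other probes. The bars differ at E12.5 (9.97% against 20.5%) and in the adult (36.8% against 24.7%).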

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

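The 33 results were recomputed under the alternatives, which gave 606 recomputed values, each for a single result under a single alternative. Many of these values come from leaving out single arrays. No change of a named probe and no lincRNA odds ratio changed its direction or its side of the threshold. In all, 587 of the 606 values kept the direction and the side of the threshold or stayed within 1.5 times the reported count. The other 19 were counts that moved further. The named probes were chosen for the largest changes in these same data, so their direction could hardly turn. Counts were compared by their totals only, so a turn in the balance of rises and falls does not enter this tally. Alternatives without E12.5 replicate 2 and P21 replicate 1 together, with array weights, with E12.5 replicates 1 and 3 averaged, those for lincRNA probes and intervals, and each array left out for the stage of the highest mean and the changes of at least 8-fold were chosen after the data were seen. Treat against a 2-fold change called 1807, 1148, 798, 2384 and 2989 probes in the adjacent intervals in order of age, fewer by construction, since it tests each change against 2-fold. Array weights, estimated gene by gene because the default estimate did not converge and was not used, gave 12343 called probes from E12.5 to E15.5 and 7452 from P7 to P14. An adjusted p below 0.01 left 3195 from P7 to P14, a stricter limit, and the 6 arrays of P21 and adult alone gave 7588. Requiring a margin of 2-fold left 924, 925, 148, 217, 236 and 2718 probes by stage of the highest mean. Without E12.5 replicate 2 and P21 replicate 1, the largest rise lay between E12.5 and E15.5 for 1997 probes. The cause of the changes with array weights, with 6 arrays and without these arrays was not tested.

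With each array left out in turn, the counts ran from 26804 to 29382 over the 6 stages, 5068 to 10780 from E12.5 to E15.5, 4855 to 5553 from E15.5 to P7, 3432 to 4646 from P7 to P14, 7517 to 10136 from P14 to P21, 9869 to 13832 from P21 to adult and 21088 to 22557 between E12.5 and adult. The largest rise from E12.5 to E15.5 ran from 864 to 2095 probes, the largest fall there from 1536 to 3396 and the largest fall from P14 to P21 from 1904 to 4384. Without E12.5 replicate 2 and P21 replicate 1, 7411 of 7602 calls from E12.5 to E15.5 and 9552 of 11705 from P21 to adult remained. No probe called in any of the 6 comparisons changed sign. The changes from E15.5 to P7 and from P7 to P14 could not move, because neither array belongs to those stages. In the other comparisons the probes had been called on data that include the remaining arrays, which makes a turn of sign less likely.

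The replicate numbers were not taken to pair the arrays, because only 14 of 45 same-numbered pairs of different stages had deviations correlated above 0.1 (range −0.366 to 0.505). The mean correlation was 0.0577 for the same number and −0.0302 for different numbers. These means are not separate evidence, because deviations from a stage mean cancel over the arrays of that stage, which ties one mean to the other. The best correlation of 10 of 18 arrays was with their own number, a hint from the data that some of them share variation. The fit with the replicate block called 28129 probes over the 6 stages, 7841, 6170, 5008, 9088 and 12060 in the adjacent intervals and 22054 between E12.5 and adult, all within 1.5 times the counts without it. The alternatives that need gene names (1 probe per gene, and all those for gene lists, X-linked genes, noncoding against coding probes and opposite-strand genes) were not run. Signal over background limits the dim probes, for which no detection call was used here: 44.5% of the falls between E12.5 and adult ended and 36.4% of the rises started below 6.53. Their size may be understated where that level is background, which was not measured.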

Other observations

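The weighing of E12.5 replicate 2 and the tests of lincRNA probes that neighbour each other or share a number were chosen only after the result was seen, as were the comparisons of identifier families and number ranges. The direction of change differed between families and number ranges of the identifiers. Among ASMM9PARTA probes with a number below 2000, 275 of 332 called probes (82.8%) rose from P14 to P21, against 37.4% of the other called probes. This range was picked among 26 ranges for its direction, so no test is given. The share was 85.1% after quantile normalization again, 84.9% with each array centred on its median and 86.4% without E12.5 replicate 2 and P21 replicate 1. Their median change between E12.5 and adult was 0.70, against −0.31 for all other probes. Several other ranges went the other way. Among probes numbered from 10000 to below 14000, 1396 of 1796 called between E12.5 and adult were lower in the adult, and their median change was −1.02, with −0.86 after quantile normalization again and −0.89 with centring. Of the 26 ranges of 2000 numbers, 7 had a median change from −1.08 to −0.89. The ranges from 14000 and 16000 had smaller rises than the lowest range, with medians of 0.32 and 0.31. In each, 33.2% of the probes were called higher in the adult than at E12.5, against 46.0% in the lowest range. Among 527 probes with CUST in the identifier, 85 of 118 called from P14 to P21 rose (72.0%, against 38.7% of others). Without E12.5 replicate 2 and P21 replicate 1, 64.6% of the CUST probes called rose. The content of these ranges is not given in the sources used here.

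E12.5 replicate 2 lay apart from replicates 1 and 3 of its stage. An E15.5 sample under an E12.5 label stays open: its smallest SD of difference from an E15.5 array was 0.86, above the highest of 0.61 between E15.5 arrays but below the 1.08 and 1.09 from the other E12.5 arrays and within the spread of one stage elsewhere, which reached 1.17 at P21. Outside E12.5, only pairs with P21 replicate 1 or Adult replicate 1 differed by more than 0.61, so that spread rests on those arrays. The likeness was not particular to E15.5, since E12.5 replicate 2 differed from the P7 arrays by an SD of 0.93 to 0.99. Whether replicate 2 or the pair of replicates 1 and 3 departs from the stage was not tested. On the third principal component E12.5 replicate 2 lay at 21.38. The E15.5 arrays lay from −71.34 to −65.21 there, the P7 arrays from −46.05 to 0.9, and E12.5 replicates 1 and 3 at 160.95 and 162.3. A more advanced embryo also stays open: the best mix of the other E12.5 arrays with the E15.5 mean took a weight of 0.62 for E15.5 and left an SD of 0.66, between the limits set for and against it. A source of variation shared with other arrays may contribute. The difference of E12.5 replicates 1 and 3 from replicate 2 correlated across probes at 0.485 with that of P7 replicate 1 and at 0.406 with that of P21 replicate 1 from their stages, after removal of the directions between the E15.5, P14 and adult means but not those that involve E12.5, P7 or P21, and the highest absolute value among 27 pairs of E15.5, P14 and adult arrays was 0.203.

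Steep rises outnumbered steep falls from P14 to P21. The tables argue against a floor of background signal: among called probes with a brighter stage mean of at least 10, 44.1% of rises and 1.53% of falls reached 8-fold, and 42.8% and 11.2% without P21 replicate 1. Among all called probes the shares were 30.4% and 1.39%. The limit on brightness thus raised the share of steep rises by itself, and the argument rests on the falls, whose share barely moved. P21 replicate 1 alone is argued against too, since without it 30.3% of rises and 10.4% of falls reached 8-fold, though the number of steep falls then rose from 75 to 662. Steep rises of transcripts specific to spermatids, set against a gradual fall of transcripts of other cells as their share of the testis declines, is a possible biological explanation that was not tested, because no gene names were used here.

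More probes fell than rose from P21 to adult at 2-fold. Differences in array medians could account for part of this but not all of it. With each array centred on its median 40.3% of called probes were higher in the adult. With any of the 6 arrays left out the share stayed at or below 42.1% with centring and 44.7% with quantile normalization again. A larger difference in array-wide scale stays open, because neither rescaling can recover the true scale. The median change of all probes was still −0.20 with centring and −0.13 after quantile normalization again. Probes near the background stay open. Without the dimmest 25% of probes the share was 29.6%, but that filter ranks probes on their mean over all arrays. It removes probes that are bright only in the adult more readily than probes that are dim only there. The share of rises can therefore drop through the filter itself, and the test cannot decide. Among called probes, 35.8% of falls ended and 31.4% of rises started below 6.53. A growing share of germ cells in the testis stays open and was not tested.

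Neighbouring lincRNA exon identifiers had slightly more similar profiles than shuffled probes, which may reflect a shared source such as one transcript or locus. Such a source was not tested. The mean correlation of the 6 stage means was 0.152 between 892 pairs with consecutive numbers on the same strand, against a mean of 0.0538 for probes shuffled within strand and stratum of mean signal (one-sided permutation p = 1e-04, the smallest that 10000 permutations can give, adjusted p = 6e-04). At 5 numbers apart it was 0.0657 (permutation p = 0.21). Of probes on both strands of one number, 625 pairs had a Spearman's rho of 0.183 between their changes from E12.5 to adult (permutation p = 1e-05, the smallest that 100000 permutations can give, adjusted p = 2e-05). Both probes were called in 111 pairs, and 70 of these changed in the same direction. From E12.5 to E15.5 rho was 0.020 (permutation p = 0.622).

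Chance assignment of arrays to stages is argued against for the probes that differed over the 6 stages. Of 100 splits of the 18 arrays only 1, the real one, reached 27890 probes, and the highest of the others reached 2406. Such splits cannot separate stage from a batch or technical source shared by the arrays of one stage. For each pair of stages, 6 arrays give 10 splits, too few for a share below 0.05. The real and the highest other split called 7602 and 6 probes from E12.5 to E15.5, 5951 and 0 from E15.5 to P7, 4858 and 0 from P7 to P14, 8894 and 0 from P14 to P21, 11705 and 1180 from P21 to adult and 21919 and 33 between E12.5 and adult, and the real split gave the most in each (1 of 10).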
